A study of Homo sapiens with 6 samples.

How the data were processed

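RNA from H1 and H9 human embryonic stem cells, kept at 4% O2 or moved to 20% O2 for 7 days, was measured on 6 Affymetrix HG-U133 Plus 2.0 arrays, with 1 array per culture and oxygen level. Per the labels' protocols, each of 3 cultures maintained at 4% O2 was split between both oxygen levels, and the members of a pair were grown in the same medium and passaged at about the same time. The cultures were H1 at passage 37 (H1p37), H1 at passage 50 (H1p50) and H9 at passage 32 (H9p32), which had spent 3, 16 and 3 passages on Matrigel in medium conditioned by mouse embryonic fibroblasts. The deposited values were signal intensities per probe set on a linear scale. In the deposited table the mean intensity of each array, without the lowest and highest 2% of probe sets, was 500.1, so the arrays had been scaled to a common level. The software, background correction and summarisation behind the signals are not given in the sources used here. The instrument files deposited with the arrays placed the 4 H1 arrays in 1 hybridization and scan run and the 2 H9 arrays in another.

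The table held 54675 probe sets, all with values above 0. Through the platform annotation 41097 probe sets had 1 gene symbol, 1801 had several and 11777 were not listed, and the 62 control probe sets were set aside. Symbols were matched by Entrez number to the RefSeq gene table of assembly GRCh38.p14 for 41043 probe sets, and the other 54 kept the platform's symbol. After 59 probe sets of Y-linked genes, XIST and TSIX were left out, 41032 probe sets for 19740 genes remained. Other genes of the X chromosome were kept. Genes that only probe sets with several symbols measure were not analysed here, and no coordinates are given because the values carry no genome build.

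The medians of log2 signal of the 6 arrays lay between 6.47 and 6.94, further apart than the tolerance of 0.1 set beforehand, so the arrays were quantile normalized. Values were then floored at the 20th percentile, a signal of 22.89, and taken to log2. Each gene was represented by its probe set of highest mean, and genes with a mean log2 signal under the 40th percentile, 5.94, were dropped, which left 14018 genes. Control ratios of 3' to 5' signal, a sign of RNA integrity, were 2.94 and 2.63 for ACTB in the 4% and 20% O2 arrays of H1p37, 1.79 and 1.84 in H1p50, and 1.44 and 1.35 in H9p32. For GAPDH they were 1.20 and 1.296, 1.22 and 1.26, and 0.97 and 1.02, lower at 4% O2 in all 3 pairs.

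Oxygen was tested with limma 3.58.1 in R 4.3.3 (moderated linear model with a mean-variance trend, two-sided) as 4% minus 20% O2 with the culture as a block, which left 2 residual degrees of freedom and 7.96 with the variance prior. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The same fit gave the difference between H9 and the mean of the 2 H1 cultures, and between the H1 cultures. A fit with an added term compared the oxygen difference between the lines. The pairing comes from the labels. Arrays of 1 culture deviated together from the means of their oxygen groups, with correlations across genes of 0.48, 0.50 and 0.68 in the 3 pairs and of -0.43 to -0.03 between other arrays. For oxygen the p-values treat the 3 cultures as replicates, although 2 of them are passages of 1 line. For line and passage they rest on the spread between the arrays of 1 culture beyond the oxygen difference, so they carry no spread between cultures. Genes with a difference of at least 2-fold in each pair were also counted, beside the same count after turning the sign of 1 pair.

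The 25 gene lists, drawn from textbook knowledge, and the rule for naming genes were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Named for oxygen were the 10 genes each way with the largest differences among those called and of 1 direction in all pairs. Where too few were called, the places were filled by smallest p among genes of at least 1.5-fold and of 1 direction in all pairs. Up to 4 members of each list with the largest differences, and a set of hypoxia, stem cell and stress genes, were added, in all 143 genes. For line and passage the 5 largest differences each way were named. Alternatives covered the normalization, floor, filter, choice of probe set, variance trend, block, scan run, threshold and each culture left out. The line count without each H1 culture, the passage count without H9p32, and the list tests for line, passage and oxygen by line were added after the data were seen.

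The oxygen fit was tested on simulated data with the fitted means, culture differences and variance prior, in 20 runs of 14018 genes of which 200 were changed. It recovered 54.8% of genes changed by 1 on the log2 scale and 82.2% of those changed by 2, with 5.34% of calls false. A hypoxia list shifted by 0.6 was called in 20 of 20 runs at the preset correlation and in 0 with an estimated one, and 2 of 480 lists without a shift were called. The simulated genes varied independently, and the shift was the same in all pairs. These counts therefore do not show how often the preset correlation falsely calls lists of correlated genes. Since the estimated correlation missed the shifted list in every run, a high adjusted p with it does not count against a list. It was not simulated for line, passage or oxygen by line. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.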

Results

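Human embryonic stem cells are usually grown in air, although the early embryo develops at lower oxygen. The series asked which transcripts respond to that difference. H1 and H9, 2 established embryonic stem cell lines, were compared between 4% O2, the level at which they had been maintained, and 20% O2 after 7 days. There were 3 arrays at each level, paired by culture into H1p37, H1p50 and H9p32. Differences below are 4% minus 20% O2 on the log2 scale, with the SD over the 3 pairs unless stated otherwise.

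TXNIP, which binds and inhibits thioredoxin, was higher at 4% O2 in all 3 cultures, by 2.01 ± 0.51 (SD, n = 3) or 4.02-fold (limma, adjusted p = 0.0477). It was the only one of 14018 genes past the threshold. ARRDC4, an arrestin-domain protein related to TXNIP, followed with 1.34 ± 0.14 and an adjusted p of 0.0706. The other genes that the naming rule took for higher values at 4% O2 did not pass. Among them were the long noncoding RNA LINC00458 (2.06 ± 0.80), the neutral sphingomyelinase gene SMPD2 (1.92 ± 0.03) and IGFBP2 (1.60 ± 0.70). The immediate early transcription factor EGR1 (0.95 ± 0.40) and the mitochondrial thioredoxin reductase TXNRD2 (0.92 ± 0.27) were also taken. That these genes and ARRDC4 were higher in 3 of 3 pairs was a condition of the rule. KLF11 (0.89 ± 0.23), GPC3 (0.71 ± 0.19) and EPB41L4A-AS1 (0.66 ± 0.09) completed this group. KLF11 and EPB41L4A-AS1 each had 1 further probe set that went the other way.

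No gene passed the threshold with a lower value at 4% O2. The same rule, which fills by smallest p and not by size, took for lower values WLS, needed for secretion of WNT proteins (-1.36 ± 0.32), SVIP (1.99-fold lower on average), IGFBP3 (-0.83 ± 0.20) and the guidance factor SLIT2 (-0.77 ± 0.17). VAT1L (-0.69 ± 0.35), the mitochondrial cyclophilin PPIF (-0.68 ± 0.24), the quinone reductase NQO1 (-0.64 ± 0.07), the glutaredoxin GLRX (-0.62 ± 0.23), pleiotrophin (PTN, -0.61 ± 0.11) and CD47 (-0.60 ± 0.07) were taken as well. Of the 4 other CD47 probe sets, 1 went the other way. WLS came near the floor, at log2 4.53 at 4% O2 in H1p50. Without adjustment 1338 genes had p under 0.05, 625 of them higher and 713 lower, where 701 were expected by chance. A difference of at least 2-fold in every pair was found for 9 genes, 8 higher and 1 lower (the pyruvate carboxylase gene PC, named after its values were seen), against 12, 12 and 6 after turning the sign of H1p37, H1p50 or H9p32, so this count did not stand above its chance level. PC was at the floor on 1 array. At 1.5-fold the count was 97 against 67, 76 and 47, and 32.1% of all genes went 1 way in all 3 pairs, where 25% were expected by chance.

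The number of genes called depended on H1p37. Without this pair 144 genes passed, 108 higher and 36 lower at 4% O2, while 11 passed without H1p50 and 1, TXNIP, without H9p32, which is also the fit within the scan run of the H1 arrays. TXNIP itself lost its call in the fits without a floor, with a higher floor, without a filter, without a variance trend, without the block and with the scan run as block, with adjusted p from 0.0571 to 1.

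**Figure D1:**
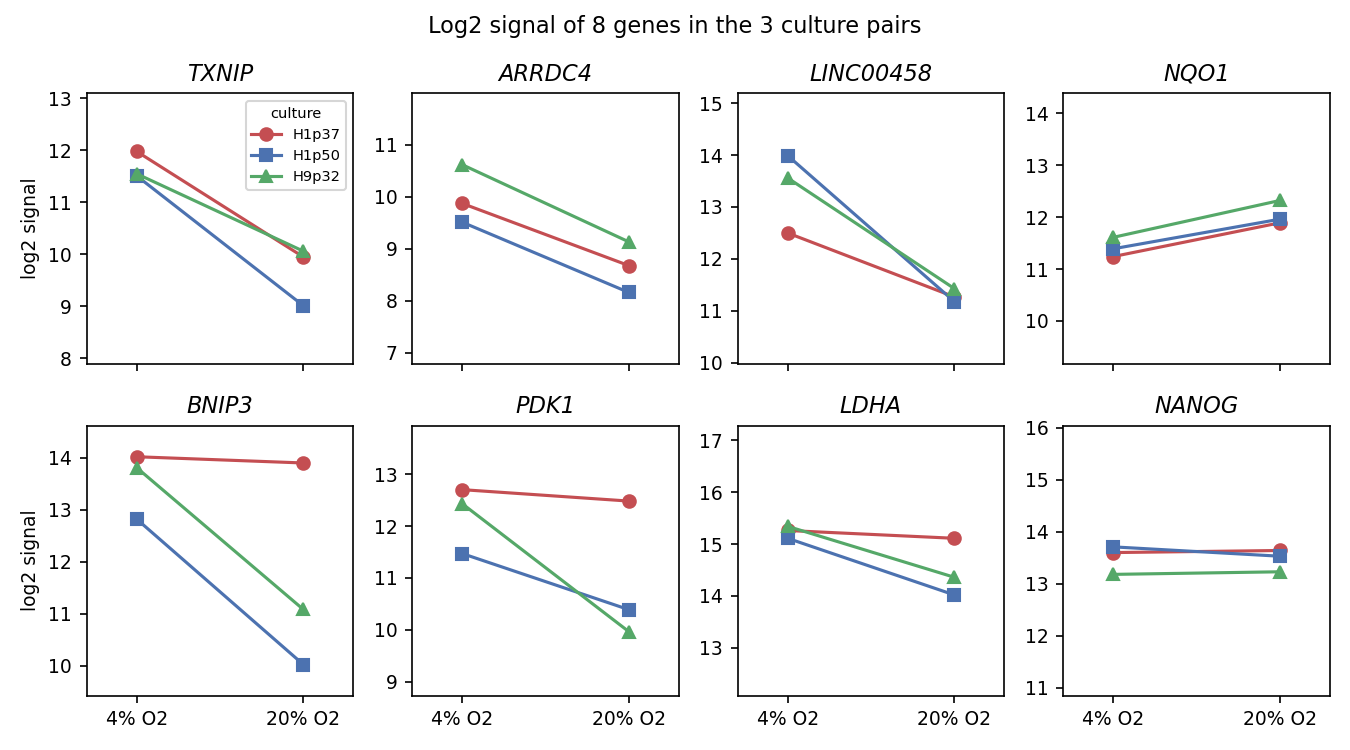
Log2 signal of 8 of the named genes (vertical axes, each spanning the same range) at 4% and 20% O2, with 1 line per culture. TXNIP, ARRDC4 and LINC00458 were higher and NQO1 lower at 4% O2 in all 3 cultures, whereas BNIP3, PDK1 and LDHA differed clearly in H1p50 and H9p32 and by 0.12, 0.22 and 0.16 in H1p37.

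Targets of the hypoxia-inducible factors, the transcription factors stabilized at low oxygen, were higher at 4% O2 as a group. Of 37 measured members 32 were higher and 5 lower, with a median of 0.64, and 16 were higher in all 3 pairs. None passed over all genes, and 18 rose when adjusted over the list alone. The list was called by camera (adjusted p = 3.95e-17), with an adjusted p of 0.725 with an estimated correlation and 0.56 by fry. In the simulated runs an estimated correlation called a list shifted by 0.6 in 0 of 20. Its adjusted p-values for oxygen, here and below, therefore do not count against a list. Its median was 0.03 in H1p37, 0.62 in H1p50 and 1.01 in H9p32. ANKRD37 (1.92 ± 1.79), the mitophagy receptor BNIP3 (1.88 ± 1.53), the stress-induced inhibitor of mTORC1 DDIT4 (1.57 ± 1.16) and PDK1 (1.25 ± 1.13), a kinase that restrains pyruvate dehydrogenase, had the largest mean differences, with SDs nearly as large as the means. VEGFA (0.65 ± 0.29) and ADM (0.56 ± 0.37), both secreted vascular factors, were higher in 3 of 3 pairs. NDRG1 (0.32 ± 0.45), the glucose transporters SLC2A1 (0.63 ± 1.21) and SLC2A3 (0.38 ± 0.45), and EGLN3 (0.40 ± 0.50) differed by less than the spread between pairs.

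Glycolysis enzymes behaved alike. Of 17 members 15 were higher at 4% O2 (median 0.43), none passed over all genes and 9 rose when adjusted over the list alone (camera, adjusted p = 2.86e-11; adjusted p = 0.725 with an estimated correlation). ALDOC (0.95 ± 0.70), ENO2 (0.78 ± 0.74), LDHA (0.74 ± 0.51) and PGK1 (0.57 ± 0.42) had the largest values. The median was 0.05 in H1p37, 0.35 in H1p50 and 0.66 in H9p32.

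Antioxidant genes and targets of NRF2, the regulator of the oxidative stress response, were lower at 4% O2. Of 26 members 24 were lower (median -0.12), 14 of them in all 3 pairs, and NQO1 alone fell when adjusted over the list alone (camera, adjusted p = 2.14e-05; adjusted p = 0.725 with an estimated correlation). The list median was -0.17 in H1p37, -0.09 in H1p50 and -0.15 in H9p32. The heme oxygenase HMOX1 (-0.69 ± 0.06), sulfiredoxin (SRXN1, -0.46 ± 0.24), GPX8 (-0.34 ± 0.27) and TXNRD1 (-0.24 ± 0.20) were lower in all 3 pairs without passing over all genes. The GAPDH ratio of 3' to 5' signal, a sign of RNA integrity, was also lower at 4% O2 in all 3 pairs (1.20 against 1.296 in H1p37, 1.22 against 1.26 in H1p50 and 0.97 against 1.02 in H9p32). It thus shared its direction with results that went 1 way in all 3 pairs. It was lower in H1p37 too, where the hypoxia and glycolysis medians were 0.03 and 0.05, so it did not follow these 2 lists by pair. The ACTB ratio was higher at 4% O2 in H1p37 and H9p32 and lower in H1p50.

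**Figure D2:**
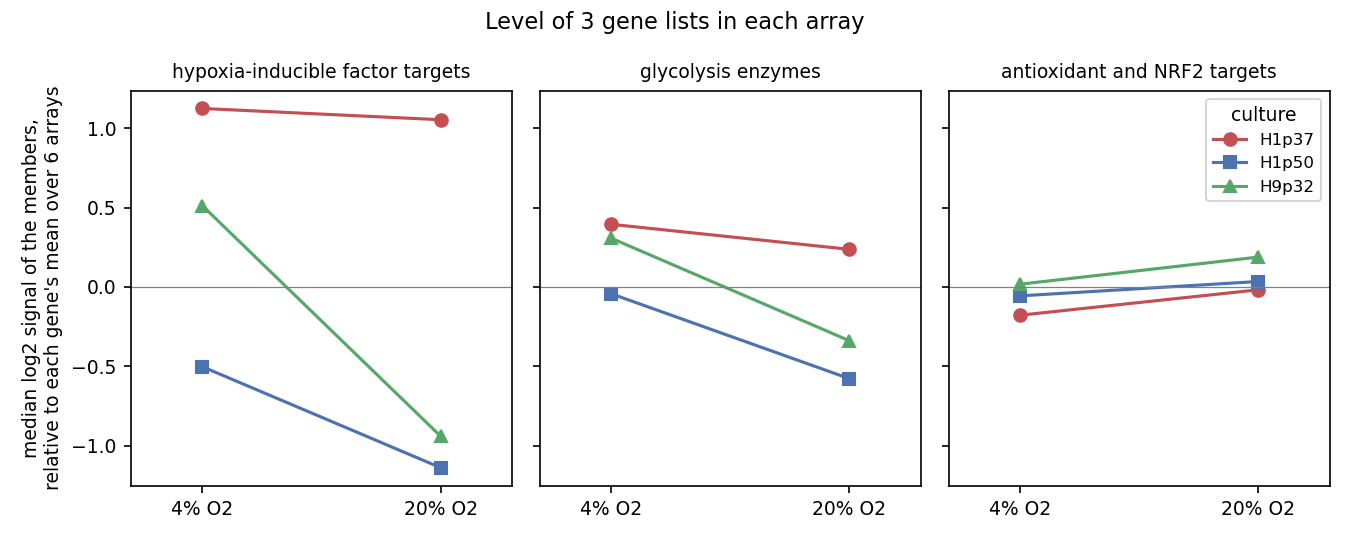
Median log2 signal of the members of 3 lists in each array, relative to each gene's mean over the 6 arrays (vertical axis), at 4% and 20% O2, with 1 line per culture. The hypoxia-inducible factor targets stood at 1.12 and 1.05 in H1p37, at -0.50 and -1.14 in H1p50, and at 0.51 and -0.94 in H9p32.

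A further 7 lists were called by camera at the preset correlation, and none with an estimated correlation (adjusted p = 0.746 with an estimated correlation for the matrix list and 0.725 for the other 6). Higher at 4% O2 were immediate early genes (median 0.18, 11 of 16 higher, adjusted p = 0.00401, medians of H1p37, H1p50 and H9p32 -0.06, 0.30 and 0.32), which include EGR1, EGR3 (0.65 ± 0.71) and KLF6 (0.44 ± 0.19). Interferon response genes were called higher too (median 0.21, 8 of 13 higher, adjusted p = 0.0175, pairs in the same order 0.19, 0.13 and -0.01). Among these, IRF7 (0.51 ± 0.37) and IFITM2 (0.43 ± 0.07) were higher, while IFI6 (-0.39 ± 0.45) and MX1 (-0.39 ± 0.46) were lower. Metallothioneins (median 0.28, 7 of 7 higher, adjusted p = 0.0175) were higher in both H1 cultures (0.42 and 0.94) and lower in H9p32 (-0.27). Matrix and collagen-modifying genes (median 0.11, 15 of 25 higher, adjusted p = 0.0201), above 0 as a list in H1p50 (0.21) but not in H1p37 (-0.03) or H9p32 (-0.02), were led by the collagen prolyl hydroxylases P3H2 (1.12 ± 0.55), P4HA1 (1.08 ± 0.67) and P4HA2 (0.79 ± 0.56) and by the lysyl hydroxylase PLOD2 (0.71 ± 0.91). P4HA1 and P4HA2 are also on the hypoxia list, and 1 further probe set of P4HA1 went the other way. Jumonji demethylases and TET genes (median 0.09, 12 of 18 higher, adjusted p = 0.0175, pairs -0.02, 0.10 and 0.24) were led by KDM3A (1.02 ± 1.01), a hypoxia target as well. Cell-cycle genes (median -0.06, 21 of 34 lower, adjusted p = 0.0474, pairs 0.00, -0.01 and -0.10) and heat shock genes (median -0.08, 9 of 12 lower, adjusted p = 0.0221, pairs -0.05, -0.14 and -0.12) were lower, with RRM2 (-0.55 ± 0.10), CCNE1 (-0.51 ± 0.07) and PCNA (-0.44 ± 0.21), all active in DNA replication, and the chaperonin HSPE1 (-0.29 ± 0.14) as examples. Adjusted over the list alone, 2 immediate early, 3 interferon, 3 matrix, 4 cell-cycle and 1 heat shock gene passed in the direction of their list, and no metallothionein or demethylase. Of the 14 alternative fits, immediate early and interferon genes were called in 10, demethylases in 9, matrix genes in 7, heat shock genes in 4 and cell-cycle genes in 2, and metallothioneins in 8 of 13. The metallothionein list had too few members to be tested without probe sets ending in _s_at or _x_at. Probe sets ending in _x_at read MT1F, MT1G and MT1H. The heat shock and cell-cycle calls were lost with the deposited values and with median centring.

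The remaining 15 lists were not called. Pluripotency genes, 24 of 30 being tested, had a median of 0.03 (adjusted p = 0.686). NANOG was at 0.03 ± 0.13, SOX2 at 0.09 ± 0.19 (1 of 3 further probe sets going the other way) and LIN28A at -0.08 ± 0.08. The members with the largest differences went both ways and did not pass. LEFTY1 (0.51 ± 0.37) and TERT (0.45 ± 0.07) were higher in all 3 pairs. FGF4 (-0.38 ± 0.33) was lower in all 3 pairs, and NODAL (-0.52 ± 0.79) varied in sign. POU5F1 had no probe set with a single gene symbol and was not tested. Medians for differentiation genes were negative, at -0.25 for mesoderm and endoderm (adjusted p = 0.131), -0.62 for 9 trophoblast genes (adjusted p = 0.191) and -0.09 for neural and ectoderm genes (adjusted p = 0.573), with TBX3 (-1.67 ± 0.91), APOA2 (-1.36 ± 0.56) and PAX6 (-1.20 ± 0.46) lower and POU3F1 (1.10 ± 1.06) higher in all 3 pairs. TBX3, APOA2 and POU3F1 were at the floor on 2, 1 and 1 arrays. These medians changed sign, to 0.08 for mesoderm and endoderm without H9p32, 0.02 for neural genes with every probe set and 0.23 for trophoblast genes with the stricter filter. By pair, mesoderm and endoderm genes had medians of -0.16, 0.13 and -0.82 in H1p37, H1p50 and H9p32. In the same order trophoblast genes had -0.29, 0.13 and -0.64, and neural and ectoderm genes -0.20, -0.06 and -0.25. Mesoderm and endoderm genes passed as lower in 2 of the 14 fits, with median centring and without H1p50. Respiratory chain subunits (-0.05, adjusted p = 0.0731), cholesterol synthesis (0.05, adjusted p = 0.0631), p53 targets (-0.02, adjusted p = 0.461) and cytosolic ribosomal proteins (0.02, adjusted p = 0.38) were near 0. Ribosomal proteins passed as higher with the deposited values (0.06) and with median centring (0.09). Cholesterol synthesis passed as higher in 3 of the 14 fits (median centring, every probe set and without H1p50) and p53 targets as lower in 2 (every probe set and without H1p50). Without H1p50 the respiratory chain, trophoblast and stromal lists also passed as lower, and the unfolded protein and amino acid stress list as higher, while without H1p37 that list passed as lower. Fibroblast and stromal markers had a median of -0.03 (adjusted p = 0.836). WNT (-0.04, adjusted p = 0.702), FGF (-0.05, adjusted p = 0.942) and TGF-beta pathway genes (-0.01, adjusted p = 0.686) did not pass, nor did unfolded protein and amino acid stress genes (0.01, adjusted p = 0.686). Of the WNT members 9 were higher and 13 lower, with an unadjusted p under 0.05 for 3 and 4 of them. NKD1 (-1.30 ± 0.46), DKK1 (-1.18 ± 0.89) and RNF43 (-1.03 ± 0.71) were lower in all 3 pairs. NKD1 and DKK1 came near the floor, at log2 4.60 at 4% O2 in H9p32 and 4.99 at 4% O2 in H1p50. Oxygen-sensing hydroxylases and HIF subunits (median -0.01, mean 0.06, test direction higher, adjusted p = 0.573) and Notch genes (median 0.00, mean -0.06, test direction lower, adjusted p = 0.942) differed in sign between measures. In the former, EGLN1 (1.13 ± 0.84), an oxygen-sensing prolyl hydroxylase, was higher in 3 of 3 pairs, and HIF1A (-0.15 ± 0.11) and EPAS1 (-0.77 ± 0.99) did not pass. Adjusted over the list alone, 4 WNT genes passed (3 higher, 1 lower), none of them NKD1, DKK1 or RNF43. In the same way 2 FGF genes, 1 neural and 1 oxygen-sensing gene passed as higher, and 1 stromal marker as lower.

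**Figure D3:**
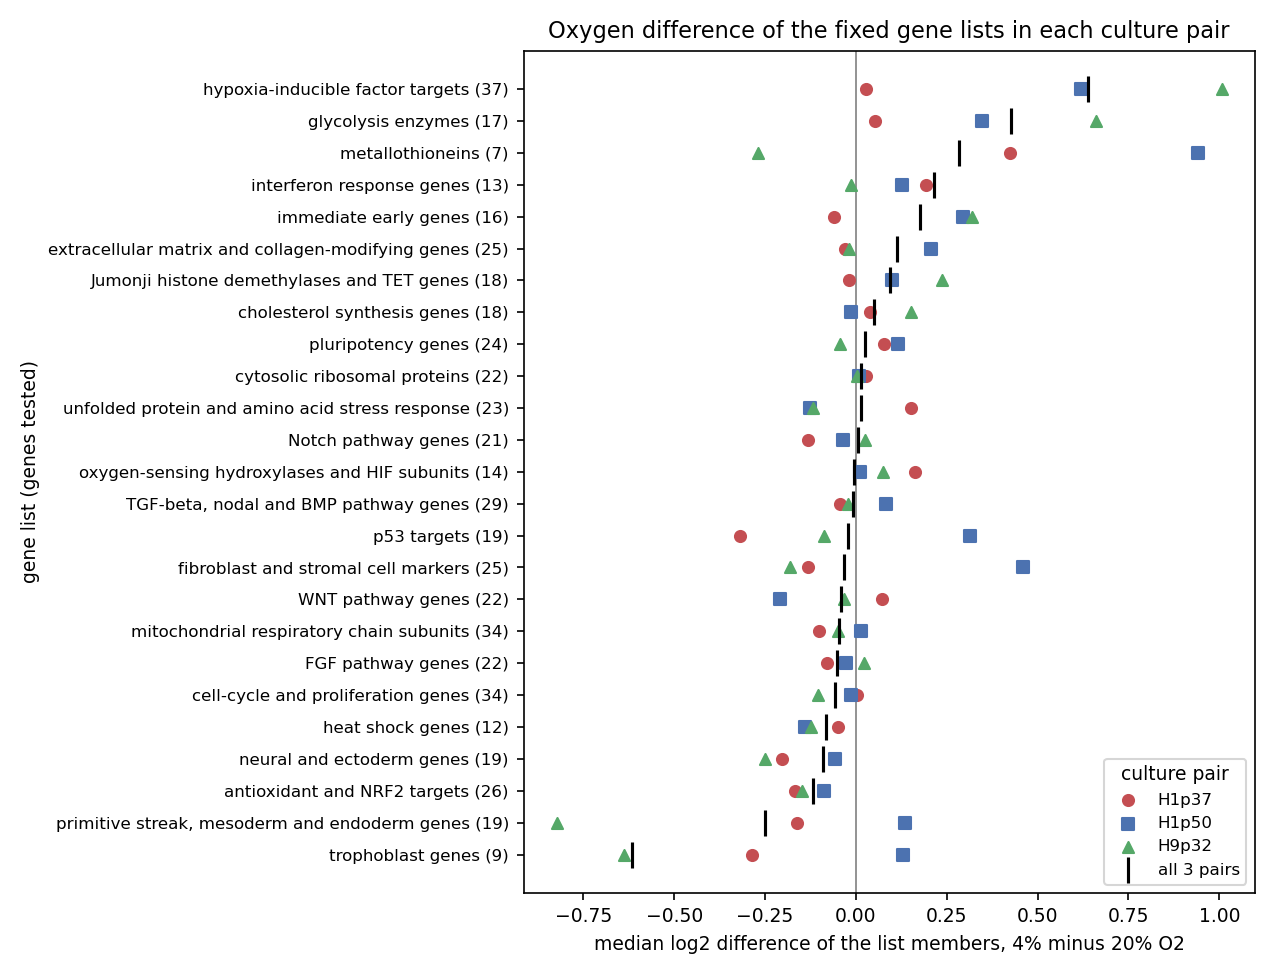
Median log2 difference, 4% minus 20% O2, of the members of each of the 25 lists (horizontal axis) in each culture pair (coloured points) and for the mean over pairs (black bar), with the number of genes tested in brackets. Hypoxia-inducible factor targets and glycolysis enzymes lay near 0 in H1p37 and above 0.3 in H1p50 and H9p32, and the antioxidant list lay below 0 in all 3 pairs.

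Whether the oxygen difference varied between the lines was tested with 1 H9 pair against 2 H1 pairs. No gene was called by limma, 360 had an unadjusted p under 0.05, and the smallest adjusted p was 0.551 for DNAJC15, a mitochondrial co-chaperone that was lower at 4% O2 in H9p32 (-3.31 or below, since the 4% O2 array was at the floor) and less so in H1p37 (-0.16) and H1p50 (-0.61). SLC2A1, PDK1, FAM162A and PFKFB3 had the next smallest p, with differences between the lines of 1.95, 1.81, 1.64 and 1.61, larger in H9p32.

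H9p32 differed from the H1 cultures in many genes. Of 3569 called, 1767 were higher and 1802 lower in H9p32, and 948 of them differed at least 2-fold. Without the filter 319 were called, and without the variance trend 980. These p-values carry no spread between cultures. The matrix gene COL3A1 (4.57 ± 0.42, SE) and NLRP2 (5.21 ± 0.27, SE) were higher in H9p32. HHLA1 was at least 42.5-fold higher, the matrix gene LUM at least 26.2-fold and the collagenase MMP1 at least 21.6-fold, with 4, 3 and 1 of the 4 H1 arrays at the floor. LOC151760 (-5.06 ± 0.29, SE) was lower. DNAJC15, MTLN and GPR141, each at the floor on 1 H9 array, were at least 44.8-fold, 26.9-fold and 22.7-fold lower, and NME8, at the floor on both, at least 29.6-fold. With an estimated correlation no list was called for line, the smallest adjusted p being 0.81. Of 25 fibroblast and stromal markers 17 were called higher and 2 lower (median 0.77, camera adjusted p = 7.11e-06; adjusted p = 0.847 with an estimated correlation). The control ratios of 3' to 5' signal also moved with this contrast, for GAPDH 0.97 and 1.02 in H9p32 against 1.20 or more in H1, and for ACTB 1.44 and 1.35 against 1.79 to 2.94. Of 19 mesoderm and endoderm genes 9 were higher and none lower (median 1.62, adjusted p = 0.000108), and of 23 unfolded protein and amino acid stress genes 16 were higher (median 0.56, adjusted p = 7.30e-08). Metallothioneins (0.76, adjusted p = 0.00158) and antioxidant genes (0.21, adjusted p = 0.0438) were the other lists called. Median centring gave 5958 genes, 5100 higher and 858 lower, and moved the median of all genes to 0.31, from 0.00 after quantile normalization. H9 was 1 culture, hybridized and scanned apart from H1, so line, culture and scan run cannot be told apart.

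The H1 cultures differed from each other in 1388 genes, 613 higher and 775 lower in H1p50, of which 491 were at least 2-fold (101 higher, 390 lower). This compares 1 culture with 1 culture, and the p-values and SEs carry no spread between cultures. Median centring gave 796 higher and 612 lower, and leaving out H9p32 gave 714 genes, 235 higher and 479 lower. Hypoxia-inducible factor targets were lower in H1p50 than in H1p37 over both oxygen levels, with a median of -2.10 and 32 of 37 members called lower (camera, adjusted p = 9.23e-27; adjusted p = 0.517 with an estimated correlation). Fibroblast and stromal markers moved with it (-1.02, 13 of 25 lower, adjusted p = 1.32e-09; adjusted p = 0.517 with an estimated correlation), and so did the ACTB ratio of 3' to 5' signal, at 2.94 and 2.63 in H1p37 against 1.79 and 1.84 in H1p50. ANKRD37 (-4.64 ± 0.65, SE), the collagen crosslinking enzyme LOX (-4.54 ± 0.34, SE) and the transcription factor BHLHE40 (-4.03 ± 0.49, SE) are on the hypoxia list, and CD300A (-4.09 ± 0.66, SE) was also among the lowest. The VEGF co-receptor NRP1 was at the floor on both H1p50 arrays and at least 16.1-fold lower there. HIF1A was higher in H1p50 by 1.02 ± 0.08 (SE, adjusted p = 0.00233). Highest in H1p50 were LRAT (3.36 ± 0.22, SE), GPAT2 (3.30 ± 0.34, SE), MAGEA4 (3.29 ± 0.36, SE), LINC01139 (3.14 ± 0.42, SE) and NPFFR2 (at least 6.24-fold, 1 H1p37 array being at the floor).

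With an estimated correlation no list was called for passage, the smallest adjusted p being 0.517. At the preset one, glycolysis enzymes (median -0.60, adjusted p = 6.10e-09), metallothioneins (-1.92, 6 of 7 lower, adjusted p = 2.54e-08), matrix genes (-0.44, 12 of 25 lower, adjusted p = 7.57e-08) and demethylases (-0.50, adjusted p = 0.000358) were lower in H1p50. So were p53 targets (-0.38, adjusted p = 0.00121), immediate early genes (-0.65, adjusted p = 0.00145), unfolded protein and amino acid stress genes (-0.40, adjusted p = 0.0129), Notch genes (-0.33, adjusted p = 0.0185) and WNT genes (-0.22, adjusted p = 0.0364). Cell-cycle genes (0.30, 9 of 34 higher, adjusted p = 2.84e-07) and heat shock genes (0.10, adjusted p = 0.00797) were higher. The 2 cultures also differed in passages on Matrigel (3 and 16), so passage, culture and time on Matrigel cannot be told apart. No gene was called for passage without the filter or without the variance trend.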

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

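All tests in this part except the count over other splits of the arrays were chosen after the results were seen. The oxygen difference of 10 gene lists differed between H9 and H1 by camera on the difference itself, at the preset correlation only, since each had an adjusted p of 0.854 with an estimated correlation. H9 minus H1, the median was 0.86 for hypoxia-inducible factor targets, 0.31 for glycolysis enzymes, 0.30 for Jumonji demethylases and TET genes, 0.25 for cholesterol synthesis and 0.25 for immediate early genes. It was -0.83 for mesoderm and endoderm genes, -0.40 for trophoblast genes, -0.38 for fibroblast and stromal markers, -0.17 for unfolded protein and amino acid stress genes and -0.91 for metallothioneins. H9 is 1 pair, and for the hypoxia list the H1 pairs stood apart from each other (0.03 in H1p37 and 0.62 in H1p50, against 1.01 in H9p32). H9p32 lay outside the H1 pairs for every list but unfolded protein and amino acid stress genes (-0.12, against 0.15 in H1p37 and -0.13 in H1p50). For stromal markers it was near H1p37 (-0.18 and -0.13, with 0.46 in H1p50). For immediate early genes it was near H1p50 (0.32 and 0.30, with -0.06 in H1p37).

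The hypoxia-inducible factor targets were high in both arrays of H1p37, and normalization is excluded as the cause, since the list median of H1p50 minus H1p37 stayed at -1.99 with median centring and -2.06 with the deposited values. Labels exchanged between the H1p37 arrays are also argued against, by a count tried only after the first one below had not decided: exchange needs most genes to go the opposite way, but 99 of the 144 genes called without H1p37 went the same way in it (0.69, 95% interval 60.5 to 76.2%, genes taken as independent; 79 of 112 outside the hypoxia and glycolysis lists), among them TXNIP at 2.03. That both arrays came from 1 oxygen level stays open, since the 2 counts disagree. Of 95 genes outside those lists changed 2-fold in both other pairs, 51 went the same way in the first count. Its share was 0.54 (95% interval 43.1 to 64.0%). The second count outside those lists, 79 of 112, lay above an even split if genes are independent (70.5%, 95% interval 61.2 to 78.8%). No culture had 2 arrays at 1 oxygen level to show how far genes move together without an oxygen difference. Stromal or differentiated cells stay open, with their markers at -0.27 in H1p37 relative to H9p32 at 20% O2 (95% interval -0.44 to 0.16). H9p32 itself had higher stromal markers than the H1 cultures (list median 0.77). Between the H1 cultures the markers went with this explanation. Their median, H1p50 minus H1p37 over both oxygen levels, was -1.02, with 13 of 25 called lower in H1p50. A hypoxia response already on in the 20% O2 culture stays open too: that array stood above the 4% O2 array of H1p50 by a list median of 1.52, but this restates the pattern and tests nothing, and local oxygen and cell density were not measured.

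For the oxygen count, 5 of the 10 splits of the 6 arrays, the real one included, gave as many genes with the culture as block, and the highest other split gave 1 against the real 1. With 10 splits a share under 0.05 cannot be reached. Of the 4 splits that part all 3 pairs, the real one gave 1 gene and the others 0.

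The difference between H9 and H1 cannot be told apart from the scan run, because 0 runs held arrays of both lines. Both oxygen levels lie within each run, so the oxygen difference is not confounded in this way.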

How the results depend on the processing

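The line count without each H1 culture and the passage count without H9p32 were chosen after seeing the data. The cause of a change was not tested unless given. The oxygen count of 1 gene became 2 at an adjusted p under 0.1, 5 with median centring, 2 with the filter at the 60th percentile and 2 with every probe set. It became 0 without a floor, with the floor at the 40th percentile, without a filter, without the variance trend, without the replicate block, with the scan run as block, and with probe sets ending in _s_at or _x_at left out, which removes the TXNIP probe set. Leaving out each culture gave 1 to 144 genes. The count of 9 genes at least 2-fold in all pairs became 97 at 1.5-fold, 4 with the floor at the 40th percentile, 47 without a filter, 4 with the stricter filter and 18 with every probe set. Over the 2 pairs left without 1 culture it was 75 to 106, since fewer pairs have to meet the criterion. The line count of 3569 became 5958 with median centring, 319 without a filter and 980 without the variance trend, and 3771 and 4189 without an H1 culture. The passage count of 1388 became 0 without a filter, 0 without the variance trend and 714 (235 higher, 479 lower) without H9p32. The count of 0 genes for oxygen by line became 1 without a floor. The 10 lists called became 0 with an estimated correlation and 0 with fry, and 4 without a filter, with probe sets ending in _s_at or _x_at left out, without the variance trend, without the replicate block and with the scan run as block. Leaving out each culture gave 6 to 13 lists. The hypoxia list (medians 0.29 to 0.93), the glycolysis list (0.22 to 0.55) and the antioxidant list (-0.14 to -0.06) were called in all 14 alternative fits with the preset correlation. Reversed was the list of unfolded protein and amino acid stress genes, which was not called (0.01) but passed as lower at -0.11 without H1p37 (adjusted p = 0.045) and as higher at 0.046 without H1p50 (adjusted p = 0.0327). Of 1922 alternative values of the 143 named genes, 1842 kept a call or stayed uncalled within 1 SD, 56 gained a call, 6 lost one and 18 moved by over 1 SD. The sign, which can change within 1 SD, did so for 11 genes outside the fits that leave out a culture and for 17 within them. Of 399 list values 308 kept a call or stayed uncalled within 1 SD, 67 lost a call, 13 gained one and 10 moved. Low signal limits genes near the floor, such as LUM, at the floor on 3 arrays, and NRP1 on 2.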

Other observations

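These genes and counts were chosen after the data were seen. In the fit without H1p37, with 1 residual degree of freedom, 23 of 37 hypoxia-inducible factor targets and 10 of 17 glycolysis enzymes were called higher at 4% O2. ANKRD37 (2.96, adjusted p = 4.67e-06, limma), BNIP3 (2.76, adjusted p = 3.26e-09) and LDHA (1.03, adjusted p = 3.37e-06) were among them, all higher in 2 of 2 pairs. Such p-values rest on the closeness of 2 pairs and on the variance prior. With all 3 pairs the limma adjusted p of these genes was 0.383, 0.342 and 0.280. Outside the lists, the secreted glycoprotein STC1 (2.02), the endothelin receptor EDNRB (1.55), and the glycogen enzymes PGM1 (1.40) and GBE1 (1.04) were called higher. The BMP-responsive genes ID1 (-0.60) and ID2 (-0.67), the follistatin gene FST (-0.85) and ZFP42 (-0.52), a pluripotency marker, were called lower, while LEFTY1 (0.69), on both the pluripotency and the TGF-beta list, was called higher. Of 24 pluripotency genes 1 was called higher and 1 lower, and of 29 TGF-beta pathway genes 1 higher and 3 lower. Of the genes named here, ANKRD37 (-0.14), STC1 (-0.08), ID1 (0.66) and ZFP42 (0.10) went the other way in H1p37. In H1p37 99 of the 144 genes had the same sign (68.8%), with a median size of 0.25 against 0.84 in the other 2 pairs.

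The HIF1A transcript and the hypoxia target list went opposite ways between the H1 cultures, 1 culture against 1. HIF1A was higher in H1p50 by 1.02, while the target list had a median of -2.10. EPAS1, another HIF subunit, went the way of the list without passing (-0.98, limma, adjusted p = 0.169). Protein was not measured. The differences of the 3 pairs correlated weakly across genes, which are not independent replicates, at 0.01 between H1p37 and H1p50, 0.08 between H1p37 and H9p32 and 0.14 between H1p50 and H9p32.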
